A study of Drosophila melanogaster with 136 samples.

How the data were processed

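The authors hybridised labelled total RNA of dissected tissues, whole animals and S2 cells to 136 Affymetrix Drosophila Genome 2 arrays. The deposited values are signals in intensity units on a linear scale, 1 per probe set and array, for 18952 probe sets. The software, background correction and summary method behind them are not given in the sources used. The mean of the middle 96% of each array, without 2% at each end, lay between 99.839 and 99.946, so arrays were scaled to 1 trimmed mean before deposit. Per the labels each array holds RNA of 12 to 100 flies per sex or of 30 to 100 larvae, adults were 7 days old, and most samples had 1 round of amplification. The first mated and virgin spermatheca had 2 rounds, and larval trachea, eye and heart another labelling kit. The redone mated spermatheca had 1 round in 3 arrays, as the whole fly, and 2 in 1 array, as the first set. Amplification therefore differs between these groups and those they are set against, except mated against virgin and, in part, the redone set. Elsewhere it cannot be separated from tissue, nor from stage in larval against adult trachea. Adult Malpighian tubule was not analysed here.

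Each array was multiplied by 1 factor to bring its trimmed mean to 99.905, and values were used as log2(signal + 9.99), where 9.99 is 10% of that mean. Of the probe sets 183 controls were left out and 18769 analysed. A gene symbol was given by the array annotation, 13544 of them joined through the gene table: 13647 probe sets have 1 symbol, 402 have several and 4720 are not listed, and together they cover 11982 genes. A gene is represented by its brightest probe set with 1 symbol. Signal over background limits what arrays show, and low genes near the pseudocount have compressed folds.

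Samples were grouped by their labels alone. There were 44 comparisons of 4 arrays with 4: 22 of an adult tissue or S2 cells against the whole fly, 8 of a larval tissue against the whole larva, 9 of larva against adult, 2 of wandering against feeding larvae, testes against ovaries, mated against virgin spermatheca, and the redone against the first mated set. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups per fit) on probe sets that reached the 40th percentile of signal in at least 1 of the 2 groups. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 and a change of at least 2-fold. Adjusted p-values in the text are from limma or, for lists, from its camera test. Interaction terms tested whether the wandering effect differed between fat body and tubule and whether the stage effect differed between midgut and hindgut. Replicate numbers did not pair the arrays: in 0 of 44 comparisons did residuals of equal numbers correlate above 0.1 throughout (range -0.47 to 0.55), so no pairing was used. No 2 arrays held identical columns, and the highest correlation was 0.995.

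Genes were named by rules: the 4 called genes with the largest increase in each tissue comparison and the 8 with the largest changes each way in the other comparisons, among those whose arrays do not overlap between the groups; from each list its 4 largest folds and up to 3 genes that go the other way or do not pass; the 15 disease homologs with the largest folds and those that do not pass; and the 3 restricted probe sets per tissue with the highest ratio. Of these the text names a part. The 34 gene lists, for tissue markers and processes, were written from general knowledge; each was tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, the p-values adjusted over the lists of a comparison, with at least 3 tested genes. A second count in the text adjusts the limma p-values over the genes of that list alone. Probe sets restricted to 1 adult tissue have a mean signal of at least 99.905 in it, at least 4 times the mean of every other dissected tissue, and no overlap of arrays; brain and ganglion count as 1 tissue, as do the 3 spermatheca groups, and head, whole fly and S2 cells are left out. Of 67 listed fly homologs of human disease genes 46 were measured, and each was tested in the tissue where it was highest; other genes whose highest tissue mean lay within the range of the homologs were picked and tested alike. Of the list results 14 were chosen for the text after their values were seen.

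In data simulated from the mated against virgin arrays 50 probe sets each were changed 2.5-, 4-, 8- and -4-fold. The test recovered 47, 50, 50 and 49 and called 4 unchanged of 11496. On the hindgut arrays it recovered 49, 48, 50 and 50, calling 2 of 12828. Low-signal changes and gene correlation were not simulated.

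The groups, comparisons, thresholds, lists and alternatives were set before the data were examined. The alternatives were values as deposited, quantile normalization, pseudocounts of 2% (1.998) and 40% (39.96), no filter and a filter at the 60th percentile, a replicate block, 1 fit of all groups, the mean of all probe sets of a gene for lists, estimated correlation, each array left out in turn, the redone arrays in place of the first mated ones, amplification as a covariate, and other thresholds for restricted probe sets. Alternatives that leave out thoracic muscle replicate 4 and redone replicate 2, or feeding fat body replicate 4 and wandering fat body replicate 2, were added after seeing the data. The planned count of testis and ovary probe sets per chromosome, and its 4-fold alternative, were not run because no genome build is named for the array annotation. Figures were drawn with matplotlib 3.10.9.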

Results

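RNA of Drosophila melanogaster was hybridised to the arrays, 4 in each of 34 groups. From the Canton-S strain there were 22 adult groups from flies 7 days old, 9 groups from feeding third-instar larvae, and 2 from wandering third-instar larvae (the stage that leaves the food before pupariation). The last group was S2 cells, a cultured line of embryonic origin. The titles of 27 groups call the replicates biological, those of 7 say only "rep", and no label says which animals went into each, so p-values measure the spread between these samples. The number of arrays, 4 per group, limits the precision.

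The arrays share 1 trimmed mean signal, 99.9, but not 1 median. The median probe set stood at 28.4 ± 0.403 in the whole fly, 18.9 ± 1.01 in the whole larva and 5.11 ± 0.210 in the ovary. Arrays of 1 group correlated at 0.884 or above, except those labelled thoracic muscle and redone mated spermatheca, where 1 array each resembled the other group. Below, a gene's signal is its mean ± SD over 4 arrays of the first and then of the second group, and its log2 fold, with its SE, is on the log2(signal + 9.99) scale, which understates changes of low genes. Genes named for their largest folds had no overlap between the 4 arrays of either group, which 2.86% of comparisons show by chance. "Rose" and "fell" are used of genes past limma's adjusted p of 0.05 and a 2-fold change, and "higher" and "lower" of the first group.

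Lists were tested with camera at a preset correlation of 0.01 between genes; with the correlation estimated from the data, 66 of 92 list results lost their call and 26 kept their side of the threshold. Pseudocounts of 2% and 40% moved 294 of 800 and 437 of 804 named folds by over 1.5 times, mostly those of genes near background in 1 group, and quantile normalization moved 46 of 803.

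The series set each adult tissue against the whole fly. Between 4602 and 7656 probe sets were called per tissue, and 16.2% to 38.7% of the calls were higher in the tissue. Both lower ends are those of the redone spermatheca with its array in doubt; the other tissues gave at least 5002 calls and 24.5%. That share depends on the scaling: the median log2 fold of all tested probe sets lay between -0.653 and -0.0370, and after quantile normalization between -0.180 and 0.448, with 45.8% to 54.4% of the calls higher.

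**Figure D1:**
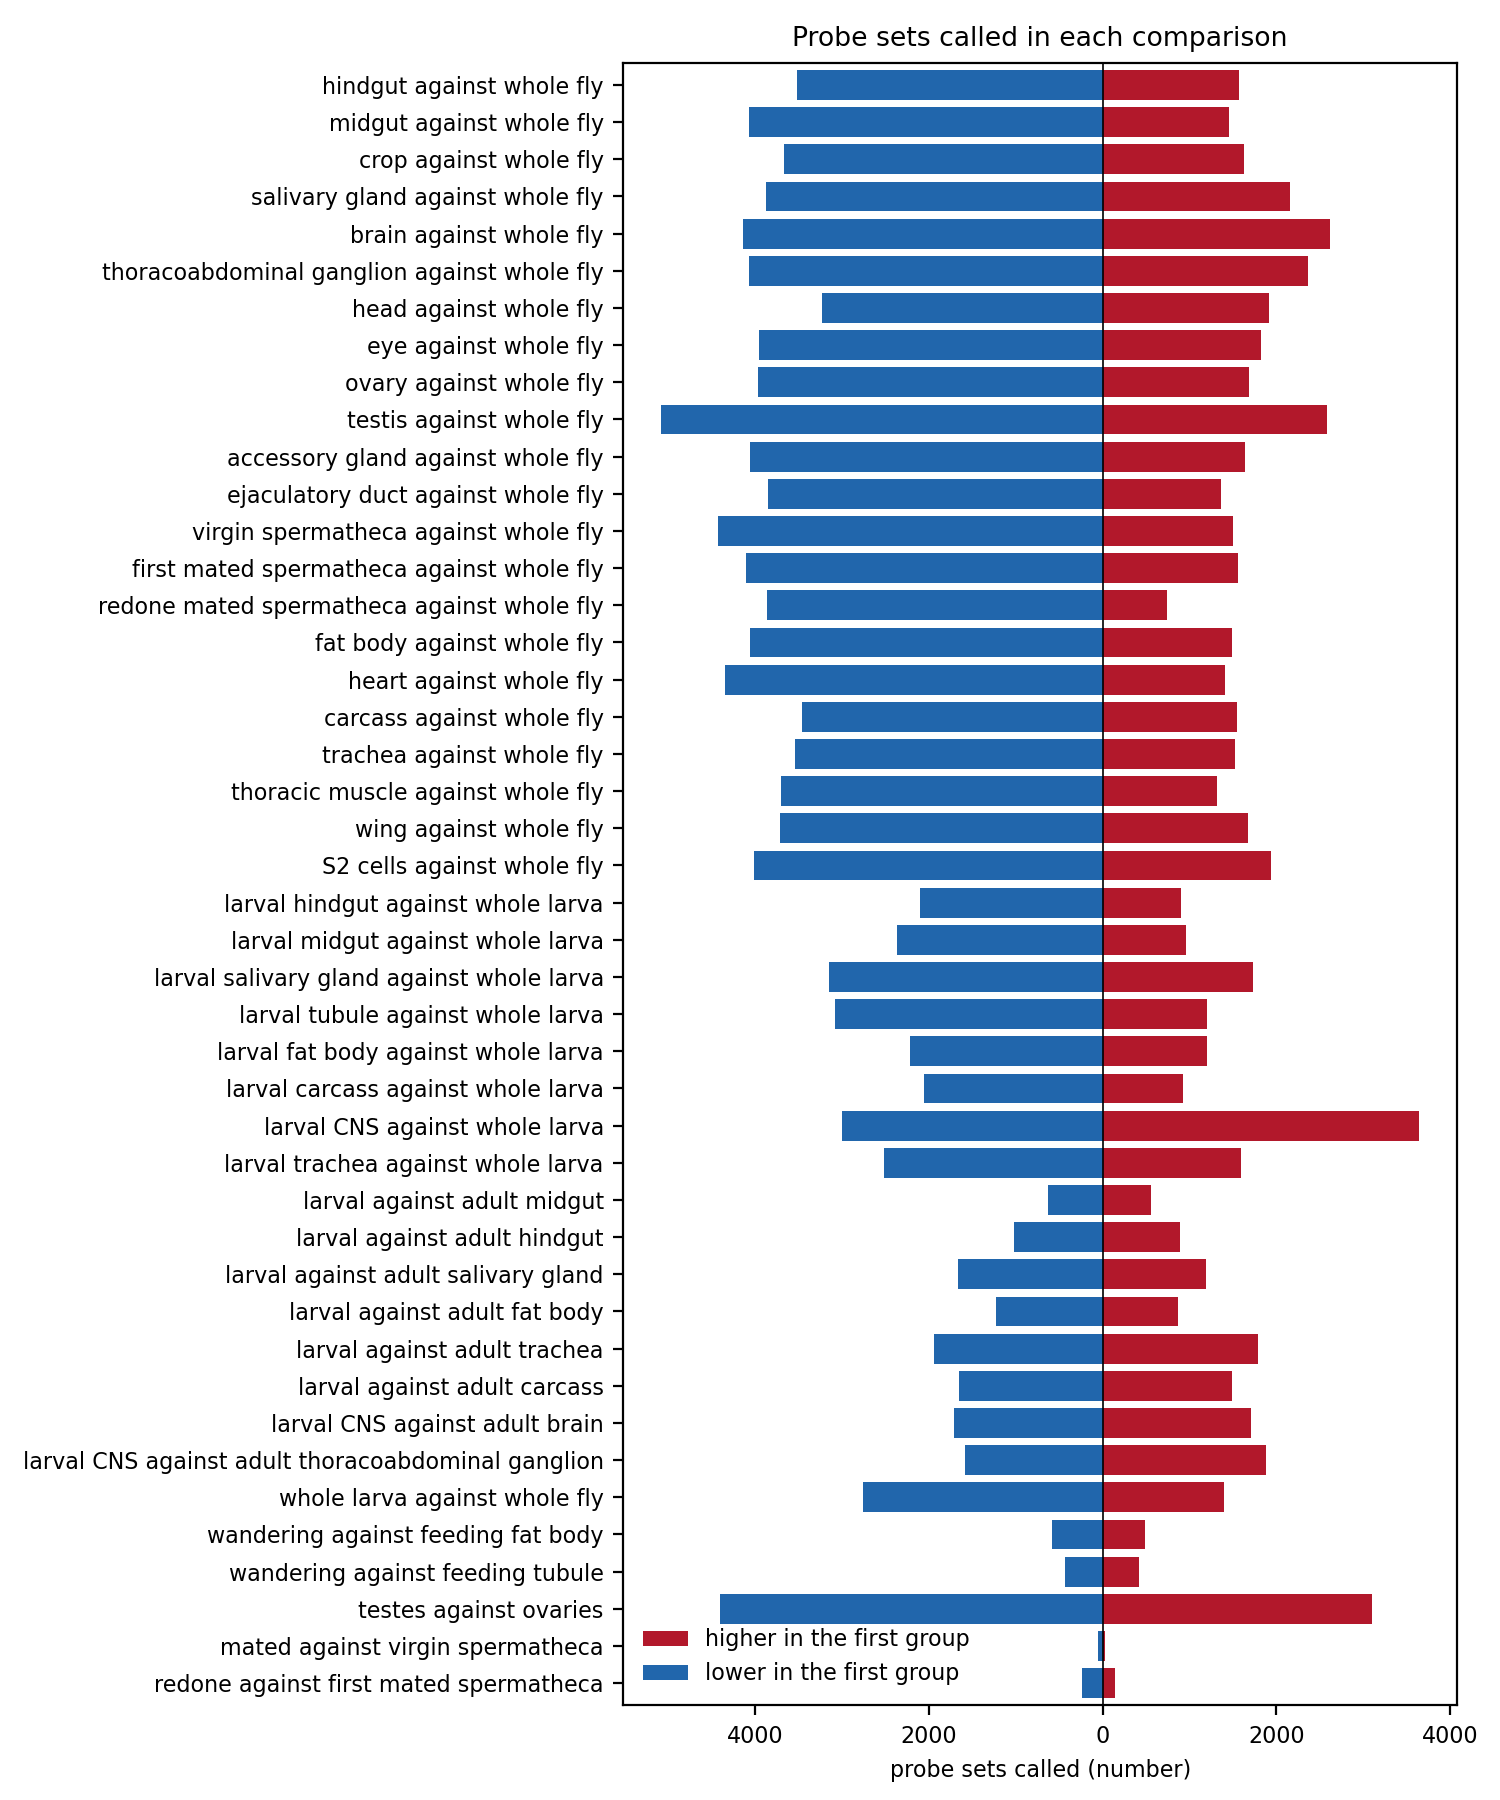
Probe sets called higher (right) and lower (left) in the first group of each of the 44 comparisons, adjusted p below 0.05 and at least 2-fold, 4 arrays against 4. The testis had the most calls against the whole fly, 2578 higher and 5078 lower, and mated against virgin spermatheca the fewest, 32 and 57.

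In the brain, genes of neurons, transmitters and glia rose. Of 23 measured neuronal genes 22 rose (22 adjusted over the list alone), none fell and 1 did not pass (adjusted p = 1e-10, and 0.14 with an estimated correlation). They included the calcium channel cac (1028 ± 150.0 against 19.0 ± 4.54, log2 fold 5.16 ± 0.14), the potassium channel Sh (log2 fold 4.90 ± 0.13) and VAChT (log2 fold 4.85 ± 0.10), which loads acetylcholine into vesicles, while nAChRalpha1 stood at 21.0 ± 4.72 against 9.95 ± 5.23 (adjusted p = 0.0094). Of 24 monoamine and peptide genes 22 rose (22 adjusted over the list alone; adjusted p = 1e-10, and 0.033 with an estimated correlation). Among them are the neuropeptides Crz (log2 fold 5.41 ± 0.11) and Pdf (4.98 ± 0.17) and the insulin-like peptide Ilp2 (4.97 ± 0.10). Of 13 glial genes 10 rose and 1 fell (the same counts adjusted over the list alone; adjusted p = 0.00012, and 0.14 with an estimated correlation), with alrm, a marker of astrocyte-like glia, at 1383 ± 84.5 against 23.6 ± 2.68 and the glial factor repo (log2 fold 3.91 ± 0.11). The largest folds of all were those of CG4409 (5.71 ± 0.15), nkt (5.53 ± 0.09) and CG1545 (5.44 ± 0.13). 2615 probe sets were higher and 4134 lower.

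The thoracoabdominal ganglion, the fused ventral nerve cord, gave 2360 higher and 4070 lower probe sets. The neuropeptide precursor FMRFa had the largest fold, 3249 ± 200.5 against 26.6 ± 8.07 (log2 fold 6.50 ± 0.16), followed by alrm (log2 fold 6.08 ± 0.10). Among neuronal genes 22 of 23 rose (22 adjusted over the list alone; adjusted p = 1.2e-09, and 0.17 with an estimated correlation). They include cac (log2 fold 4.89 ± 0.13) and futsch (4.64 ± 0.16), a microtubule-associated protein. Among monoamine and peptide genes 18 rose and 1 fell (the same adjusted over the list alone; adjusted p = 1e-06, and 0.035 with an estimated correlation). The peptide genes Lk (5.20 ± 0.08), for leucokinin, and Dh31 (4.83 ± 0.11) rose, NPF (-1.75 ± 0.21) fell (-0.80 and no call with a 40% pseudocount), and the insulin-like peptide Ilp2 stood at 18.1 ± 2.41 against 42.6 ± 6.66 (adjusted p = 2.7e-05).

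In the eye 16 of 17 phototransduction genes rose (16 adjusted over the list alone; adjusted p = 5.9e-11, and 0.094 with an estimated correlation). The lipid transfer protein rdgB (3469 ± 348 against 37.2 ± 6.66, log2 fold 6.21 ± 0.13) and the scaffold inaD (5.83 ± 0.12) led them, and rdhB (6.92 ± 0.12), a dehydrogenase of the visual pigment cycle, and the cuticle proteins Cpr49Ag (6.49 ± 0.15) and Cpr72Ec (6.39 ± 0.16) had the largest folds of all. In the head 18 of 24 monoamine and peptide genes rose (18 adjusted over the list alone; adjusted p = 1.8e-09, and 0.011 with an estimated correlation), and the phototransduction list gave 16 of 17 higher (16 adjusted over the list alone; adjusted p = 1.8e-09, and 0.11 with an estimated correlation), with inaD at 1091 ± 74.8. Of 23 olfactory and gustatory binding genes 18 rose in the head (18 adjusted over the list alone; adjusted p = 2.3e-08, and 0.11 with an estimated correlation), led by a10 (log2 fold 4.01 ± 0.18) and Obp28a (log2 fold 3.83 ± 0.15). Obp56g stood at 1951 ± 426 against 2514 ± 566 (adjusted p = 0.11). The eye gave 1823 higher and 3950 lower probe sets, the head 1914 and 3222.

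In the ovary, germline and cell cycle genes rose. Of 32 tested oogenesis genes 20 rose and 2 fell (the same adjusted over the list alone; adjusted p = 7.6e-06, and 0.16 with an estimated correlation). The anterior determinant bcd (1028 ± 43.4 against 161 ± 44.2, log2 fold 2.65 ± 0.19) had the largest fold of all genes. The piRNA pathway gene krimp (log2 fold 1.59 ± 0.09) and fs(1)N (1.90 ± 0.12) rose. By its brightest probe set, the only one used, exu (log2 fold -4.14 ± 0.12) fell (-3.52 after quantile normalization). Of 23 cell cycle and DNA replication genes 19 rose (19 adjusted over the list alone; adjusted p = 1.2e-06, and 0.2 with an estimated correlation). Examples are CycE (log2 fold 2.15 ± 0.09) and Orc1 (1.61 ± 0.11). Of 15 eggshell genes 2 rose (1 adjusted over the list alone; adjusted p = 0.16). The chorion gene Cp15 stood at 3217 ± 245 against 3366 ± 1199 (adjusted p = 0.95). There were 1680 higher and 3968 lower probe sets.

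The testis differed most from the whole fly, with 2578 higher and 5078 lower probe sets. Of 40 spermatogenesis genes 34 rose and 1 fell (the same adjusted over the list alone; adjusted p = 3e-11, and 0.33 with an estimated correlation). Among them are the mitofusin fzo (389 ± 15.5 against 22.8 ± 5.33, log2 fold 3.62 ± 0.12), the sperm aminopeptidase S-Lap5 (3.54 ± 0.09) and bol (3.42 ± 0.09), which controls meiotic entry. The stem cell daughter factor bam stood at 26.1 ± 3.37 against 51.9 ± 8.08 (adjusted p = 6.8e-05). The largest folds were those of CG43108 (4.22 ± 0.10), the atypical MAP kinase Erk7 (4.11 ± 0.11) and CG31327 (4.03 ± 0.11).

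In the accessory gland, which makes seminal fluid, all 25 measured seminal fluid genes rose (25 adjusted over the list alone; adjusted p = 1.1e-16, and 0.3 with an estimated correlation). Examples are the sex peptide network genes intr (3570 ± 154 against 27.3 ± 6.03, log2 fold 6.60 ± 0.13), antr (6.29 ± 0.11) and lectin-46Ca (6.20 ± 0.13). The largest folds belonged to CG9168 (6.81 ± 0.18) and CG32201 (6.78 ± 0.15). 1640 probe sets were higher and 4059 lower. The ejaculatory duct gave 1361 higher and 3847 lower probe sets. Of its 5 listed genes 3 rose (3 adjusted over the list alone; adjusted p = 0.0024, and 0.42 with an estimated correlation), with Gld (log2 fold 4.55 ± 0.30), a glucose dehydrogenase, and the peptide Dup99B (log2 fold 2.08 ± 0.19). Ebp stood at 6041 ± 999 against 3071 ± 466 (adjusted p = 0.00015). CG17738 (2060 ± 757 against 20.6 ± 2.96, log2 fold 6.02 ± 0.21) and CG2663 (5.91 ± 0.16) had the largest folds.

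In the midgut digestive enzyme genes rose. Of 27 trypsin-like proteases 21 rose and 1 fell (the same adjusted over the list alone; adjusted p = 3.8e-11, and 0.21 with an estimated correlation), with Ser8 (log2 fold 3.89 ± 0.15) and iotaTry (log2 fold 3.81 ± 0.22) among those that rose and Ser12 (log2 fold -3.38 ± 0.17) the one that fell. Of 22 carbohydrases and lysozymes 18 rose and 4 fell (the same adjusted over the list alone; adjusted p = 1.3e-07, and 0.23 with an estimated correlation). The alpha-glucosidase tobi (4098 ± 128 against 163 ± 70.6, log2 fold 4.65 ± 0.23) and the maltase Mal-A4 (log2 fold 4.21 ± 0.30) rose, and LysP (log2 fold -3.24 ± 0.24), the lysozyme of salivary glands, fell. CG15263 (log2 fold 5.99 ± 0.19) had the largest fold. 1451 probe sets were higher and 4068 lower.

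In the adult salivary gland the same carbohydrase and lysozyme list went mostly the other way: 17 of 22 fell and 2 rose (the same adjusted over the list alone; adjusted p = 0.0071, and 0.34 with an estimated correlation). Maltase Mal-B1 (10530 ± 2309 against 72.0 ± 40.3, log2 fold 7.11 ± 0.32) and lysozyme LysP (6.96 ± 0.23), at 22860 ± 2783, were the ones that rose, and Mal-A1 (-6.33 ± 0.16) and LManVI (-5.45 ± 0.19) fell most. The mannosidase gene alpha-Man-Ic (log2 fold 7.62 ± 0.16) had the largest fold. 2153 probe sets were higher and 3875 lower.

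The hindgut gave 1575 higher and 3514 lower probe sets. Of 28 subunits of the V-ATPase, a proton pump, 14 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.0048, and 0.26 with an estimated correlation; adjusted p = 0.08 after quantile normalization). Those that rose include Vha100-2 (log2 fold 2.36 ± 0.16) and Vha44 (2.21 ± 0.09), and those that fell Vha68-3 (-3.12 ± 0.10) and Vha36-2 (-2.37 ± 0.12), both near background in the hindgut (3.75 ± 0.930 and 0.532 ± 0.159). CG9993 (2648 ± 203 against 38.4 ± 6.76, log2 fold 5.79 ± 0.12), CG15870 (5.77 ± 0.10) and CG13177 (5.76 ± 0.13) had the largest folds. In the crop, the food store of the foregut, 0 V-ATPase genes rose and 9 fell (the same adjusted over the list alone; adjusted p = 0.93; adjusted p = 0.029 after quantile normalization). An example is Vha100-5 (log2 fold -3.41 ± 0.25). The crop's largest folds were those of CG31810 (6.22 ± 0.12), CG14356 (5.84 ± 0.09) and CG5065 (5.58 ± 0.12). 1622 probe sets were higher and 3659 lower.

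In the fat body, the fly's store of fat and glycogen, 16 of 19 fat body genes rose and 1 fell (the same adjusted over the list alone; adjusted p = 4.8e-10, and 0.15 with an estimated correlation). The methyltransferase Gnmt (3512 ± 583 against 124 ± 30.8, log2 fold 4.72 ± 0.18) had the largest fold of all genes, followed within the list by fit (3.40 ± 0.21) and the lipid transfer protein Apoltp (3.18 ± 0.14). The lipophorin gene apolpp stood at 5923 ± 778 against 3103 ± 368 (adjusted p = 7e-05). Of 9 tested antimicrobial peptide genes 1 rose and 4 fell (the same adjusted over the list alone; adjusted p = 0.9), with Drsl5 (log2 fold -5.61 ± 0.21) and the defensin Def (log2 fold -3.45 ± 0.56) falling. There were 1489 higher and 4051 lower probe sets.

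In the heart Amnionless (2966 ± 344 against 1.45 ± 1.24, log2 fold 8.02 ± 0.12) and Cubn2 (7.13 ± 0.17), which form the endocytic receptor of nephrocytes, lectin-33A (7.97 ± 0.21) and the cardiac factor Hand (7.35 ± 0.15) had the largest folds. Of 11 tested heart genes 7 rose (7 adjusted over the list alone; adjusted p = 0.00054, and 0.12 with an estimated correlation). Examples are H15 (log2 fold 2.67 ± 0.19) and tup (2.20 ± 0.12), at 2.79 after quantile normalization. Muscle genes were split, with 6 of 22 higher and 5 lower (the same adjusted over the list alone; adjusted p = 0.0052, and 0.5 with an estimated correlation; the direction turned after quantile normalization, adjusted p = 0.81). Their median log2 fold was 0.66 and their mean -0.42, while camera pointed up. The troponin T gene up (log2 fold 2.11 ± 0.14) rose, and the leg and flight muscle genes TpnC41C (log2 fold -5.51 ± 0.17) and TpnC4 (log2 fold -5.25 ± 0.31) fell. Hemocyte genes rose, 16 of 19 (16 adjusted over the list alone; adjusted p = 8.8e-10, and 0.088 with an estimated correlation), and so did fat body genes, 17 of 19 higher and 1 lower (the same adjusted over the list alone; adjusted p = 8.8e-10, and 0.12 with an estimated correlation), led by Gnmt (log2 fold 4.36 ± 0.16). In all 1405 probe sets were higher and 4339 lower.

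The tracheal arrays of adults carried the same 4 leading genes as the heart: lectin-33A (log2 fold 7.68 ± 0.30), Amnionless (6.95 ± 0.30), Hand (6.62 ± 0.26) and Cubn2 (6.09 ± 0.31). Of 15 tracheal genes 4 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.02, and 0.43 with an estimated correlation). Among them are btl (162 ± 118 against 2.30 ± 1.46, log2 fold 3.57 ± 0.41), the FGF receptor of tracheal cells, and Gasp (log2 fold 2.72 ± 0.27). Markers of other cells rose with them: 17 of 19 hemocyte genes (adjusted p = 1.5e-10, and 0.43 with an estimated correlation), 9 of 19 fat body genes (the same for both adjusted over the list alone; adjusted p = 0.00047, and 0.43 with an estimated correlation; 0.059 after quantile normalization) and 4 of 21 tested neuronal genes (1 adjusted over the list alone; adjusted p = 0.00069, and 0.51 with an estimated correlation). Without trachea replicate 4 18 neuronal genes rose (adjusted p = 9.4e-07, and adjusted p = 0.46 with an estimated correlation), while 4 tracheal genes rose and 2 fell (0.034 and 0.46). The carcass gave 1550 higher and 3452 lower probe sets, against 1524 and 3540 in trachea. In the carcass 19 of 22 muscle genes rose (19 adjusted over the list alone; adjusted p = 9.6e-09, and 0.3 with an estimated correlation). They include fln (log2 fold 2.15 ± 0.27) and the actin Act79B (log2 fold 1.99 ± 0.15), at 1.31 after quantile normalization. Of 10 tested cuticle genes 1 rose, the pupal-adult cuticle gene Acp65Aa (log2 fold 2.34 ± 0.56), and 2 fell (1 and 0 adjusted over the list alone; adjusted p = 0.52); their median log2 fold was -0.32 and their mean -0.17, while camera pointed up. The storage protein Lsp2 (895 ± 241 against 24.3 ± 7.14, log2 fold 4.71 ± 0.21) had the largest fold.

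Of the 4 arrays labelled thoracic muscle, 3 carried flight muscle genes at high level and replicate 4 did not. All 4 together gave 1317 higher and 3702 lower probe sets, and 2 of 22 muscle genes higher with 5 lower (the same adjusted over the list alone; adjusted p = 0.037, and 0.65 with an estimated correlation). That list call ended without replicate 1, 2 or 3 (adjusted p = 0.099, 0.12 and 0.088), and its direction turned after quantile normalization (0.88). Oxidative phosphorylation genes rose, 23 of 24 (23 adjusted over the list alone; adjusted p = 4.3e-11, and 0.24 with an estimated correlation). Examples are ND-75 (8934 ± 5820 against 525 ± 54.4, log2 fold 3.44 ± 0.84) of complex I and ATPsynD (log2 fold 3.05 ± 0.59) of ATP synthase (2.73 and 1.57 after quantile normalization, 4.43 and 3.72 without replicate 4). Without replicate 4, an alternative chosen after seeing the data, 2284 probe sets were higher and 4397 lower, and 15 muscle genes rose while 5 fell (adjusted p = 1.4e-05, and adjusted p = 0.18 with an estimated correlation). In those 3 arrays the flight muscle actin Act88F stood at 10830 ± 4189 and flightin (fln) at 16170 ± 4058, while replicate 4 gave 2.28 and 9.93. The genes with the largest folds were then ND-B8 (5214 ± 904, log2 fold 5.92 ± 0.33), the mitochondrial carrier Rim2 (5.57 ± 0.24) and pHCl-1 (5.57 ± 0.15). With all 4 arrays Rim2 gave 4.57 ± 0.86.

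The wing gave 1671 higher and 3716 lower probe sets. CG12483 (3250 ± 132 against 13.3 ± 6.34, log2 fold 7.17 ± 0.17), CG18537 (7.03 ± 0.15) and CheA84a (6.90 ± 0.09), of a chemosensory family, had the largest folds. Olfactory and gustatory binding genes went both ways: 10 of 23 rose and 11 fell (the same adjusted over the list alone; adjusted p = 0.28). Obp19b (log2 fold 5.52 ± 0.11) and Obp57b (4.91 ± 0.14) were higher and Obp56g (-6.61 ± 0.25) and Obp83b (-4.67 ± 0.13) lower. Their median log2 fold was -0.57 and their mean -0.06, while camera pointed up. Of 18 tested neuronal genes 9 rose and 1 fell (the same adjusted over the list alone; adjusted p = 6.3e-05, and 0.39 with an estimated correlation); the GABA receptor Rdl (log2 fold 2.68 ± 0.24) rose and Gad1 (log2 fold -3.86 ± 0.22), which makes GABA, fell.

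The spermatheca, the female sperm store, was sampled in 3 groups. In virgins Send2 (1412 ± 412 against 5.38 ± 3.11, log2 fold 6.51 ± 0.21) and Send1 (log2 fold 5.59 ± 0.25), spermathecal endopeptidases, and Hr39 (log2 fold 2.06 ± 0.13), the receptor needed for the gland, rose and Gld (log2 fold -4.02 ± 0.28) fell, 3 and 1 of 5 listed genes (the same adjusted over the list alone; adjusted p = 0.013, and 0.22 with an estimated correlation; adjusted p = 0.061 after quantile normalization). The largest fold was that of the protease CG17234 (log2 fold 7.10 ± 0.18). Of 19 fat body genes 13 rose and 3 fell (the same adjusted over the list alone; adjusted p = 2.8e-06, and 0.057 with an estimated correlation). Gnmt (log2 fold 4.63 ± 0.21) and fit (3.59 ± 0.16) were higher and Cyp4g1 (-6.87 ± 0.27), a P450 of oenocytes, lower. In the first mated set the same list of 5 gave 3 higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.015, and 0.3 with an estimated correlation; 0.074 after quantile normalization and 0.054 with the mean of all probe sets of a gene), with Send2 at 3250 ± 2011. The redone set, made again by the authors, gave 2 and 1 (the same adjusted over the list alone; adjusted p = 0.063), and without its replicate 2 3 and 1 (adjusted p = 0.0079, and adjusted p = 0.25 with an estimated correlation). In its 3 other arrays Send2 reached 10640 ± 1263, in replicate 2 5.26. The 3 groups gave 1498, 1556 and 747 higher and 4423, 4105 and 3855 lower probe sets. Without replicate 2 the redone set gave 1420 and 4276.

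**Figure D2:**
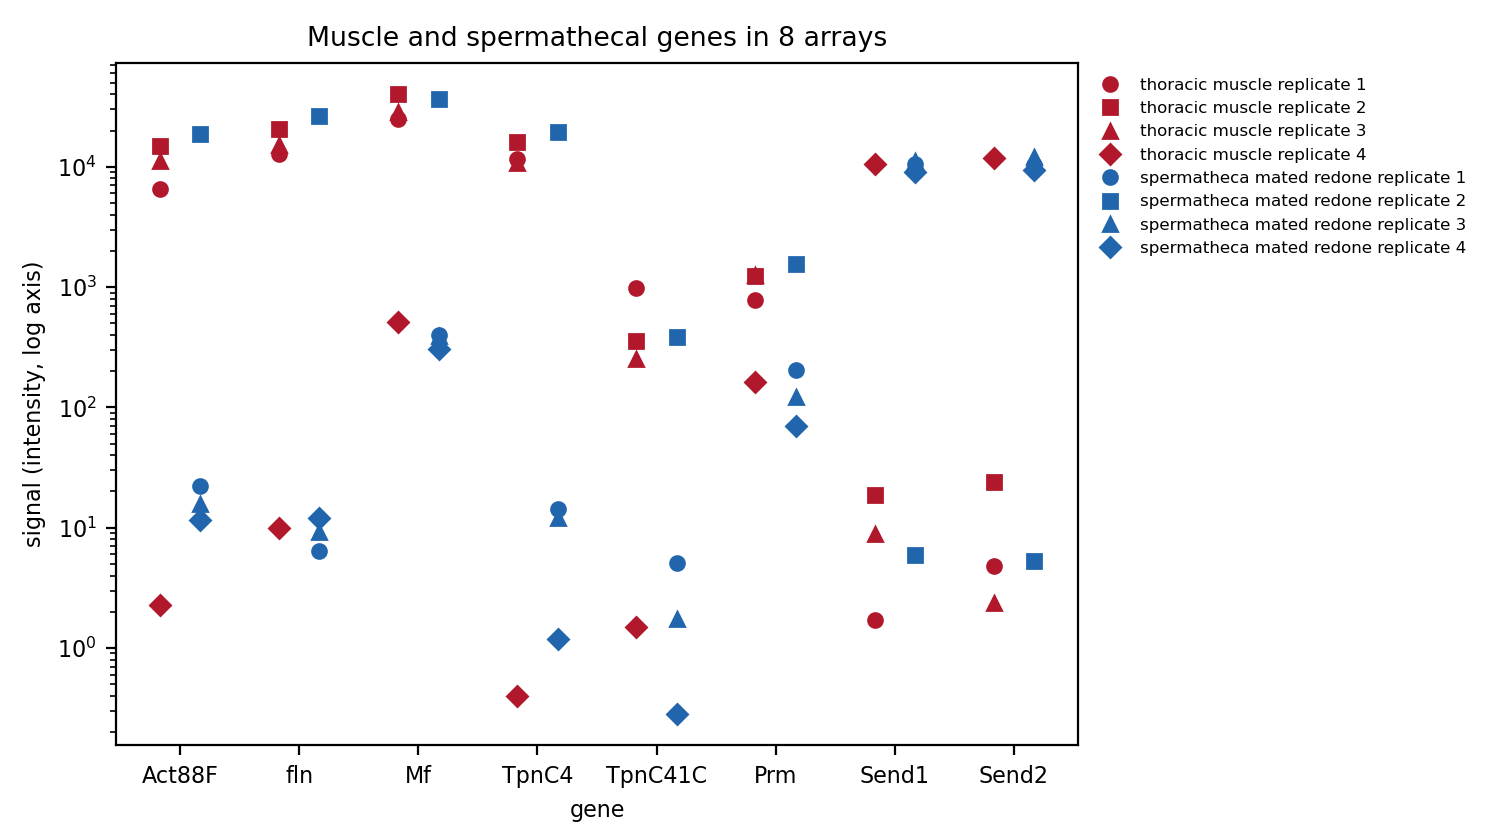
Signal (log axis) of 6 muscle and 2 spermathecal genes in each array labelled thoracic muscle and redone mated spermatheca, 1 point per array. Thoracic muscle replicate 4 lies at 2.28 for Act88F and 11720 for Send2, and redone replicate 2 at 18680 and 5.26.

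S2 cells showed hemocyte genes. Of 17 tested 13 rose and 1 fell (the same adjusted over the list alone; adjusted p = 7.5e-05, and 0.15 with an estimated correlation), led by the prophenoloxidase PPO1 (2458 ± 109 against 83.7 ± 21.9, log2 fold 4.75 ± 0.16) and the collagen Col4a1 (log2 fold 3.55 ± 0.16). Of 23 cell cycle genes 3 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.72): the mitotic kinesin Klp61F (log2 fold 1.34 ± 0.11) rose, CycB (log2 fold -1.55 ± 0.08) fell. Of 40 ribosomal protein genes 1 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.13), those that fell being duplicates such as RpS5b (log2 fold -5.24 ± 0.12) and RpL10Aa (log2 fold -3.23 ± 0.11). Their median log2 fold was 0.08 and their mean -0.20, while camera pointed up. Among the largest folds were those of CG14273 (7.12 ± 0.09), CG10232 (6.92 ± 0.10) and the growth factor Pvf2 (6.35 ± 0.17). 1934 probe sets were higher and 4010 lower.

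**Figure D3:**
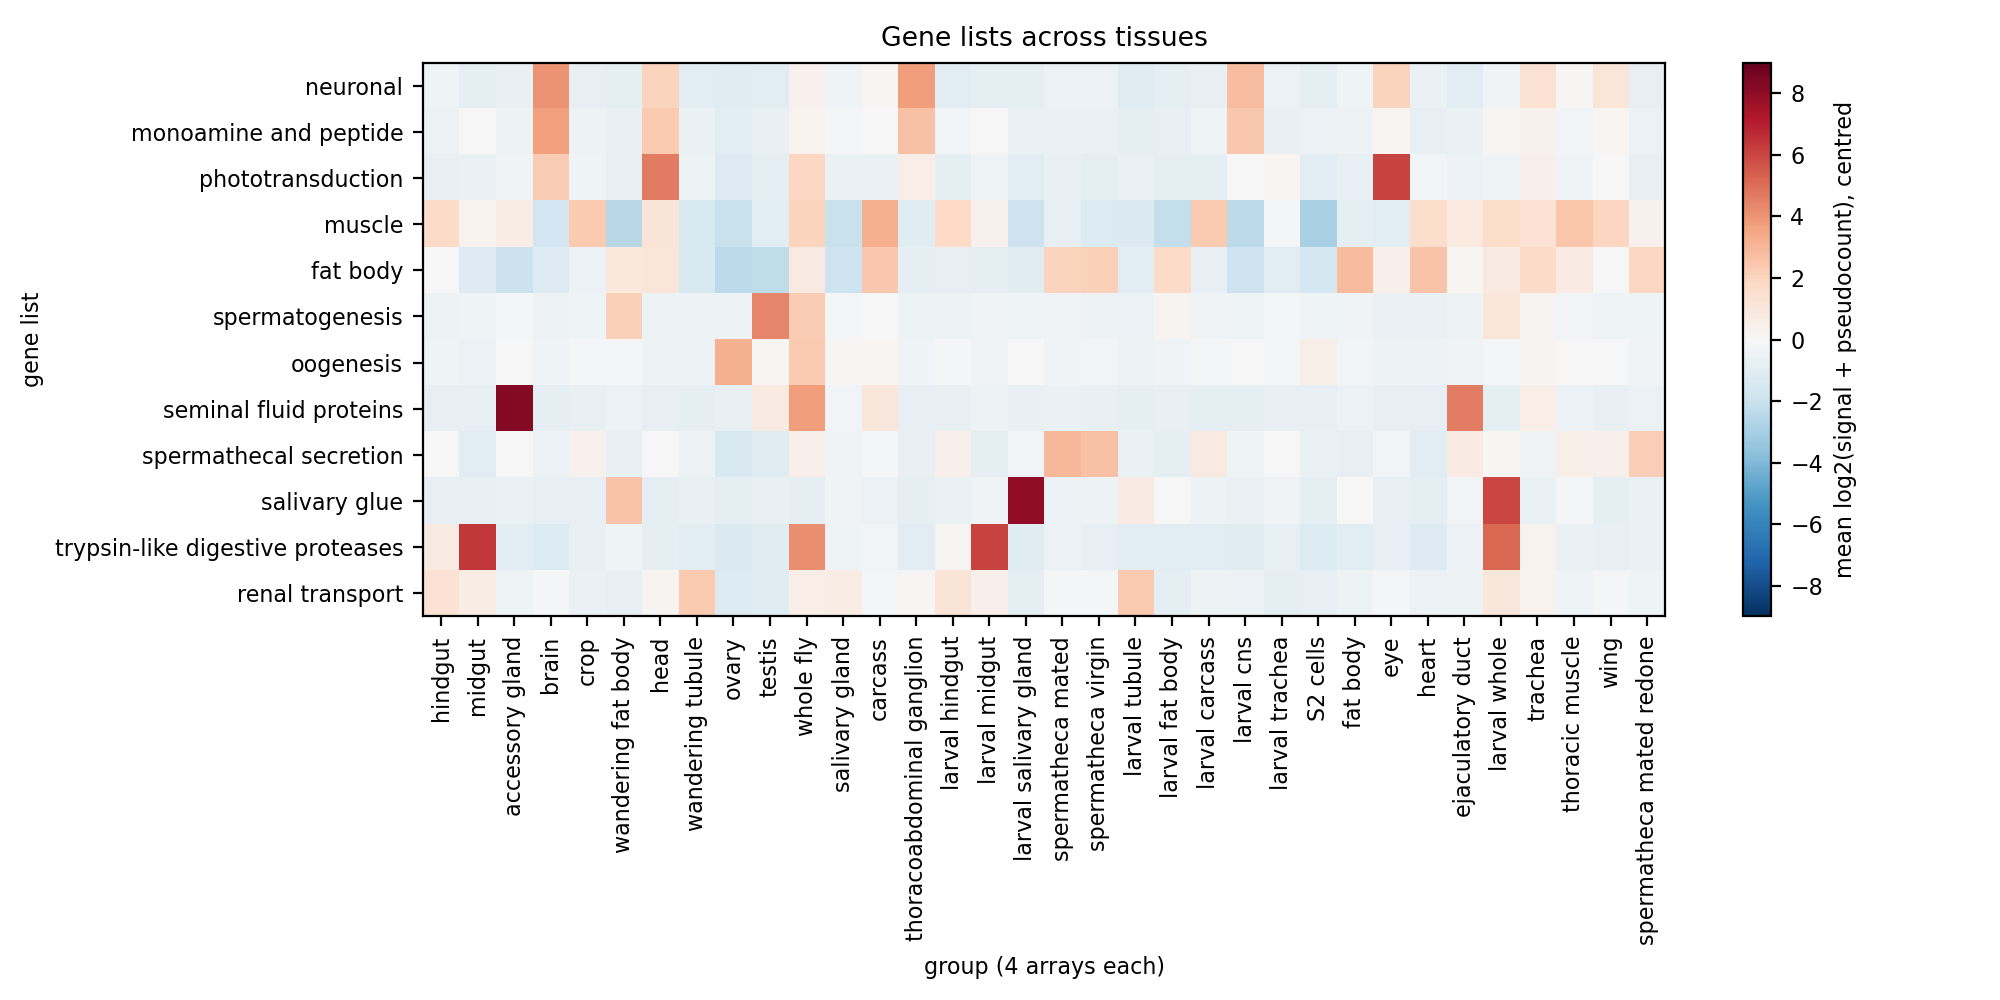
Mean log2(signal + 9.99) of 12 gene lists in the 34 groups, each list centred on its mean over the groups. Seminal fluid genes are highest in the accessory gland (12.80), phototransduction genes in the eye (11.30) and glue genes in the larval salivary gland (12.41).

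Larval tissues were set against the whole feeding larva, with 2984 to 6636 probe sets called; 28% to 54.9% of calls were higher in the tissue, and 39.3% to 56.8% after quantile normalization. In the larval CNS both neuronal and proliferation genes rose. 20 of 23 neuronal genes rose (20 adjusted over the list alone; adjusted p = 5.5e-06, and 0.14 with an estimated correlation), with Gad1 (1296 ± 60.8 against 45.8 ± 4.19, log2 fold 4.55 ± 0.08) and onecut (log2 fold 4.57 ± 0.21). All 23 cell cycle genes rose (23 adjusted over the list alone; adjusted p = 2.1e-06, and 0.13 with an estimated correlation). Among them are CycE (log2 fold 2.86 ± 0.13) and Mcm3 (2.44 ± 0.08). Ank2 (4.81 ± 0.21), an ankyrin of axons, and OtopLa (4.78 ± 0.11) had the largest log2 folds. 3644 probe sets were higher and 2992 lower.

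In the larval salivary gland 10 of 12 glue genes rose (10 adjusted over the list alone; adjusted p = 6.5e-05, and 0.23 with an estimated correlation), led by ng1 (9538 ± 1285 against 1037 ± 139, log2 fold 3.19 ± 0.13) and Sgs1 (log2 fold 3.06 ± 0.18). Sgs7 stood at 7341 ± 1373 against 3855 ± 403 (adjusted p = 0.00021). CG32073 (log2 fold 5.60 ± 0.21) and CG34276 (log2 fold 5.39 ± 0.10) had the largest folds, with 1731 higher and 3149 lower probe sets.

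The larval Malpighian tubule, the insect kidney, gave 1201 higher and 3082 lower probe sets. Of 23 renal transport genes 15 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.00034, and 0.078 with an estimated correlation). The potassium channel Irk3 (2588 ± 129 against 61.8 ± 10.1, log2 fold 5.19 ± 0.11), the organic anion transporter Oatp58Da (4.57 ± 0.09) and the zinc transporter ZnT35C (4.44 ± 0.09) rose. The metallothionein MtnB (-6.91 ± 0.19) fell. Of 27 tested V-ATPase genes 7 rose and 6 fell (the same adjusted over the list alone; adjusted p = 0.027, and 0.61 with an estimated correlation; 0.21 after quantile normalization). Vha100-2 (log2 fold 1.53 ± 0.08) was higher and Vha100-4 (log2 fold -3.95 ± 0.12) lower. In the larval hindgut the same list gave 6 and 4 of 27 (the same adjusted over the list alone; adjusted p = 0.12; 0.0012 with the mean of all probe sets of a gene), again with Vha100-2 (log2 fold 1.56 ± 0.08) higher. CG44098 (log2 fold 4.63 ± 0.12) was among its largest folds. 902 probe sets were higher and 2096 lower.

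In the larval midgut 12 of 26 tested trypsin-like proteases rose (12 adjusted over the list alone; adjusted p = 5.5e-10, and 0.3 with an estimated correlation). An example is alphaTry (6153 ± 540.5 against 1858 ± 379, log2 fold 1.74 ± 0.15). Of 22 carbohydrases and lysozymes 12 rose and 2 fell (the same adjusted over the list alone; adjusted p = 8e-04, and 0.48 with an estimated correlation): Mal-A1 (log2 fold 2.90 ± 0.26) rose, Mal-A5 (log2 fold -4.98 ± 0.19) fell. The drosomycin-like peptide gene Drsl2 (log2 fold 4.54 ± 0.65) had the largest fold. 963 probe sets were higher and 2365 lower.

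In the larval fat body 14 of 18 tested fat body genes rose and 3 fell (the same adjusted over the list alone; adjusted p = 0.00013, and 0.29 with an estimated correlation). Apoltp (1884 ± 222 against 229 ± 18.1, log2 fold 2.98 ± 0.12), Mtp (2.97 ± 0.09) and the perilipin Lsd-1 (2.52 ± 0.13) rose and Cyp4g1 (-5.61 ± 0.20) fell. The serine protease teq (log2 fold 4.03 ± 0.64) and NimC2 (3.91 ± 0.23), a phagocytosis receptor family member, had the largest folds. Replicate 4 of the feeding fat body also carried testis transcripts. There were 1205 higher and 2218 lower probe sets.

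The larval carcass gave 928 higher and 2056 lower probe sets, with the largest fold in CG7906 (log2 fold 5.68 ± 0.80). Of 18 tested cuticle genes 7 rose (7 adjusted over the list alone; adjusted p = 0.031, and 0.53 with an estimated correlation). An example is Pcp (2949 ± 668 against 452 ± 119, log2 fold 2.68 ± 0.21). The call ended with the mean of all probe sets of a gene (adjusted p = 0.1), without carcass replicate 1 (0.08) and without whole larva replicate 4 (0.064). Of 20 tested muscle genes 7 rose (7 adjusted over the list alone; adjusted p = 9.3e-05, and 0.53 with an estimated correlation), with sls (log2 fold 1.55 ± 0.22), the titin of flies, and Mlc2 (log2 fold 1.44 ± 0.15), which lost its call in 1 fit of all groups (adjusted p = 0.082). The adult flight muscle actin Act88F stood at 14.4 ± 3.80 against 11.8 ± 2.95 (adjusted p = 0.36). In the larval trachea 7 of 15 tracheal genes rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.059), with btl (log2 fold 3.81 ± 0.12) and the chitinase Cht2 (log2 fold 2.28 ± 0.08). The defensin Def (log2 fold 5.96 ± 0.39) and ETH (log2 fold 5.84 ± 0.15), the ecdysis-triggering hormone of the Inka cells on tracheae, had the largest folds. 1591 probe sets were higher and 2509 lower.

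Feeding larvae were next set against adults; folds are larval over adult. In the nervous system the larval CNS exceeded the adult brain in proliferation genes: all 23 rose (23 adjusted over the list alone; adjusted p = 1.7e-10, and 0.098 with an estimated correlation), led by the replication clamp PCNA (848 ± 62.1 against 5.14 ± 3.73, log2 fold 5.85 ± 0.16) and CycB (log2 fold 5.69 ± 0.13). The importin Pen (log2 fold 6.70 ± 0.07) and nerfin-1 (6.38 ± 0.09), a factor of newborn neurons, rose as well. Of 23 neuronal genes 14 fell and none rose (14 lower adjusted over the list alone; adjusted p = 1.4e-05, and 0.22 with an estimated correlation). Among them are Dscam2 (log2 fold -3.03 ± 0.17) and the synaptobrevin nSyb (-2.52 ± 0.16). Of 24 monoamine and peptide genes 15 fell and 2 rose (the same adjusted over the list alone; adjusted p = 0.00025, and 0.33 with an estimated correlation): the convertase amon (log2 fold -5.05 ± 0.11) and the clock peptide Pdf (log2 fold -3.30 ± 0.18) fell, CCAP (log2 fold 1.13 ± 0.08) rose (0.77 and no call with a 40% pseudocount). The yolk protein gene Yp1 (log2 fold -7.29 ± 0.11) had the largest decrease, at 2788 ± 377 in the dissected adult brain. Counts were 1712 and 1713. Against the adult ganglion all 23 cell cycle genes rose too (23 adjusted over the list alone; adjusted p = 5e-10, and 0.19 with an estimated correlation), the chromosomal passenger gene borr (log2 fold 5.51 ± 0.12) and Ilp5 (log2 fold 5.47 ± 0.17) rose. 1882 probe sets were higher and 1579 lower.

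In the salivary glands all 12 glue genes rose (12 adjusted over the list alone; adjusted p = 2.9e-11, and 0.11 with an estimated correlation), with Sgs3 (10310 ± 1359 against 2.28 ± 1.55, log2 fold 9.71 ± 0.14), at 10.36 after quantile normalization, and ng1 (log2 fold 9.59 ± 0.19). The adult gland held CG33109 (3.96 ± 4.58 against 21610 ± 2158, log2 fold -10.64 ± 0.20), the lipocalin NLaz (-9.84 ± 0.27) and Mal-B1 (-9.29 ± 0.18). There were 1189 higher and 1665 lower probe sets.

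In the midgut 3 of 26 trypsin-like proteases rose and 4 fell (the same adjusted over the list alone; adjusted p = 0.45): Jon66Cii (log2 fold 3.64 ± 0.10) was larval and Ser8 (log2 fold -5.99 ± 0.12) adult. Of 22 carbohydrases and lysozymes 12 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.024, and 0.71 with an estimated correlation), with Mal-A7 (log2 fold -6.55 ± 0.36) and tobi (log2 fold -5.40 ± 0.40) lower and the lysozyme LysS (log2 fold 5.85 ± 0.12) higher. CG34282 (7158 ± 481 against 3.32 ± 1.42, log2 fold 9.08 ± 0.10), CG5084 (9.05 ± 0.10) and the mucin Muc96D (8.86 ± 0.17) marked the larva. CG5107 (-8.37 ± 0.22) and Muc68D (-7.67 ± 0.19) marked the adult. The counts were 559 and 627; a pseudocount of 2% gave 1890 in all. In the hindgut 1 of 22 tested V-ATPase genes rose, Vha100-5 (log2 fold 1.62 ± 0.11), and none fell (1 adjusted over the list alone; adjusted p = 0.83); their median log2 fold was -0.03 and their mean 0.04, while camera pointed down. CG7299 (log2 fold 8.11 ± 0.08) and the storage protein Lsp2 (7.16 ± 0.23) were larval. The sodium pump subunit nrv3 (-7.47 ± 0.08) and Yp1 (-7.57 ± 0.26) were adult, with 886 and 1015 called. Lists of other tissues moved too: larval serum (3 of 3) and tracheal genes (11 of 15, 1 lower) rose and yolk genes (3 of 3) fell. Whether these come from the hindgut was not tested. The stage difference itself differed between midgut and hindgut for 2025 probe sets by an interaction test, 1035 with a higher and 990 with a lower effect in the midgut. CG5084 differed by 9.06 ± 0.11 on the log2 scale, with a stage fold of 9.05 in midgut and -0.01 in hindgut, and CG17192 by -8.14 ± 0.19.

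In the fat body 2 of 19 fat body genes rose and 4 fell (the same adjusted over the list alone; adjusted p = 0.56), with a median log2 fold of 0.06 and a mean of -1.18, and camera pointed down: fit (4.08 ± 3.34 against 4237 ± 990.4, log2 fold -8.23 ± 0.22), the P450 Cyp4g1 (log2 fold -7.98 ± 0.23) and the fatty acid synthase FASN2 (log2 fold -7.26 ± 0.17) were adult, and regucalcin (log2 fold 2.30 ± 0.15) larval. Fbp1, the receptor for storage proteins, had the largest larval fold, at 7244 ± 1060 against 6.64 ± 9.45, followed by Fbp2 (log2 fold 8.72 ± 0.22). Of 9 tested antimicrobial peptide genes 1 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.78), CecB (log2 fold 3.03 ± 0.70) (3.68 without feeding replicate 1) and Drsl4 (log2 fold -2.24 ± 0.33). Counts were 869 and 1222.

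Larval and adult trachea were labelled with different kits, so stage and labelling cannot be separated there. In the trachea 11 of 15 tracheal genes rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.00016, and 0.23 with an estimated correlation). The chitin synthase kkv (1283 ± 138 against 14.9 ± 3.89, log2 fold 5.71 ± 0.16) and obst-A (5.69 ± 0.19) were higher and the scavenger receptor Sr-CI (-2.82 ± 0.22) lower. The cuticle protein Cpr47Ec (log2 fold 8.65 ± 0.18) had the largest larval and CG16826 (-9.41 ± 0.44) the largest adult fold, with 1785 and 1941 called. In the carcass 9 of 19 tested cuticle genes rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.0027, and 0.35 with an estimated correlation), led by Lcp9 (log2 fold 7.91 ± 0.27) and Lcp65Aa (log2 fold 5.81 ± 0.25). The adult carcass held Yp2 (log2 fold -9.13 ± 0.15), the desaturase Fad2 (-8.45 ± 0.17) and the calcium-binding Scp1 (-8.10 ± 0.15), with 1495 and 1653 called.

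Between whole larvae and whole flies 1400 probe sets were higher and 2760 lower (33.7% higher, and 48.9% after quantile normalization). Of 16 tested cuticle genes 7 rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.00051, and 0.26 with an estimated correlation), led by Lcp9 (log2 fold 7.76 ± 0.17). Of 16 phototransduction genes 11 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.0013, and 0.26 with an estimated correlation): the arrestin Arr2 (4.89 ± 2.74 against 2277 ± 234, log2 fold -7.28 ± 0.14) fell and the carotenoid receptor ninaD (log2 fold 4.27 ± 0.27) rose. Glue gene Sgs3 (log2 fold 8.62 ± 0.08) was larval. The seminal protein Acp98AB (-8.42 ± 0.11), Yp1 (-8.41 ± 0.15) and the eggshell gene Vm34Ca (-8.06 ± 0.24) were adult.

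Both wandering groups entered the series in an earlier block of samples than both feeding groups, so batch and stage cannot be told apart. The tubule pools held 30 wandering and 50 feeding larvae. Between wandering and feeding larvae, in the fat body 489 probe sets were higher and 578 lower (45.8% higher, 34.8% after quantile normalization). CG9812 (4031 ± 1113 against 15.4 ± 4.16, log2 fold 7.29 ± 0.22), the scavenger receptor santa-maria (6.80 ± 0.30) and the peptide gene Drsl5 (6.27 ± 0.34) rose most. The globin glob1 (-4.52 ± 0.35), Nplp2 (-3.81 ± 0.23) and ACC (-3.63 ± 0.13), the first enzyme of fatty acid synthesis, fell. Of 17 tested ecdysone response genes 6 rose (6 adjusted over the list alone; adjusted p = 0.011, and 0.95 with an estimated correlation; 0.071 without feeding replicate 4 and 0.11 without the 2 arrays named next). They include the transporter E23 (log2 fold 3.35 ± 0.26) and the receptor Eip78C (log2 fold 2.68 ± 0.31). EcR stood at 188 ± 17.6 against 226 ± 41.1 (adjusted p = 0.31). Of 19 autophagy genes 2 rose (2 adjusted over the list alone; adjusted p = 0.29), Atg7 (log2 fold 1.97 ± 0.19) and Atg1 (log2 fold 1.52 ± 0.33).

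Of 10 tested salivary glue genes 2 passed (8 adjusted over the list alone; adjusted p = 0.14; 0.024 with the mean of all probe sets of a gene, 6.9e-05 without wandering replicate 2 and 0.017 without feeding replicate 3). Sgs3 stood at 2283, 1445 and 2205 in wandering replicates 1, 3 and 4, at 2.98 in replicate 2, and at 2.18 to 93.4 in feeding arrays. Of 35 tested spermatogenesis genes 1 passed (19 adjusted over the list alone; adjusted p = 5.3e-05, and 0.95 with an estimated correlation). The testis signal, in percent of the adult testis, was 2.28, 34.42, 10.14 and 7.06 in the wandering arrays and 9.78 in feeding replicate 4, against -0.06 to 0.06 in the other feeding arrays. Without feeding replicate 4 and wandering replicate 2, an alternative chosen after seeing the data, 1649 probe sets were higher, 1014 of them restricted to the testis among adult tissues, and 575 lower; 25 of 34 spermatogenesis genes and 8 of 10 glue genes then rose (adjusted p = 2.6e-09 and 0.00082, and adjusted p = 0.96 for both with an estimated correlation). In 1 fit of all groups the count was 2444, and without feeding replicate 4 alone 2170.

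**Figure D4:**
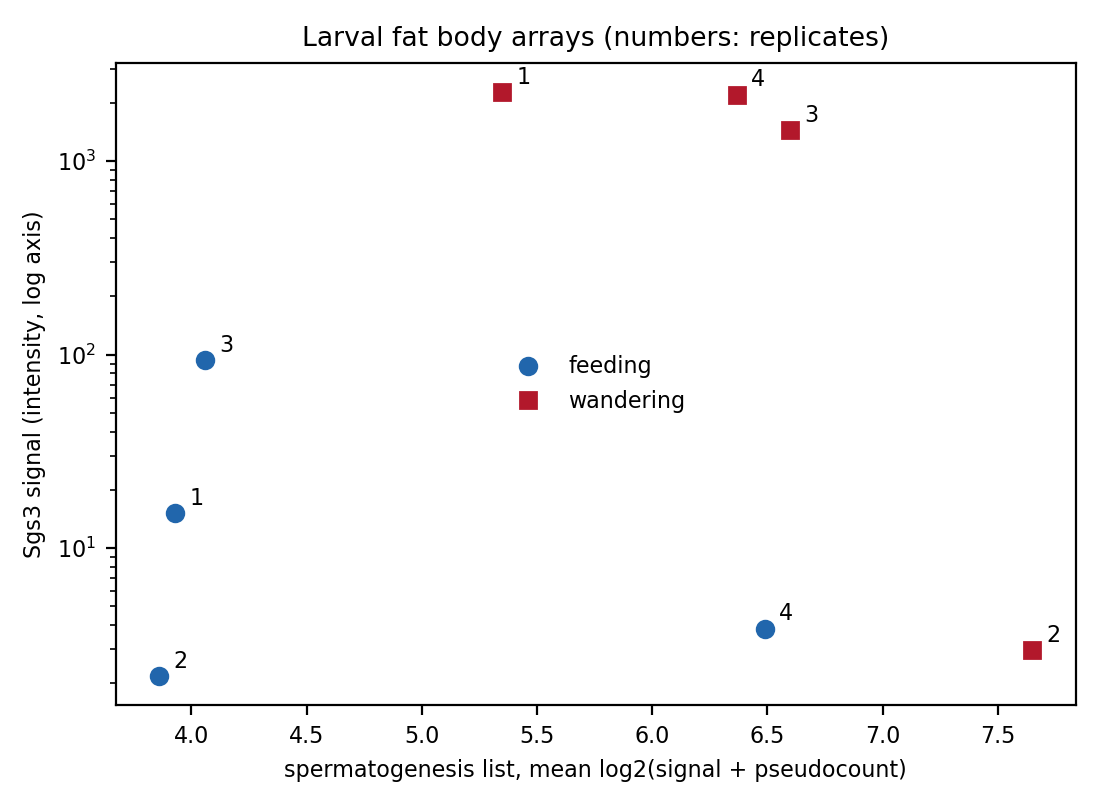
Mean log2(signal + 9.99) of the spermatogenesis list (x) and signal of the glue gene Sgs3 (y, log axis) in the 8 larval fat body arrays, 1 point per array. Feeding replicate 4 lies at 6.49 on the x axis and the 3 other feeding arrays between 3.86 and 4.06.

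In the tubule 417 probe sets were higher and 433 lower. Of 19 tested ecdysone response genes 5 rose (5 adjusted over the list alone; adjusted p = 0.024, and 0.6 with an estimated correlation; 0.072 with the mean of all probe sets of a gene), with Eip78C (log2 fold 2.11 ± 0.22), E23 (log2 fold 2.07 ± 0.21) and the zinc finger gene br (log2 fold 1.54 ± 0.23). Of 23 renal transport genes 1 rose (1 adjusted over the list alone; adjusted p = 0.85), and the anion transporter Oatp58Dc stood at 2090 ± 129.7 against 3669 ± 245 (adjusted p = 6.9e-05). Their median log2 fold was 0.06 and their mean 0.05, while camera pointed down. CG34296 (489 ± 170.0 against 8.49 ± 5.18, log2 fold 4.73 ± 0.27) and the C/EBP factor slbo (3.46 ± 0.33) rose. CG10553 (-4.16 ± 0.41), Ldsdh1 (-3.50 ± 0.18) and the calcium-binding smp-30 (-3.48 ± 0.24) fell. The wandering effect differed between fat body and tubule for 1047 probe sets by an interaction test, 471 with a higher and 576 with a lower effect in fat body, and for 2184 without the 2 arrays named above, 2183 without feeding fat body replicate 4 and 1743 without wandering fat body replicate 1. CG9812 differed by 7.17 ± 0.30 and GstT3, a glutathione transferase, by -4.29 ± 0.31, with folds of -2.68 in fat body and 1.61 in tubule.

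Testes and ovaries differed in 3095 higher and 4398 lower probe sets. Of 40 spermatogenesis genes 36 rose and 2 fell (the same adjusted over the list alone; adjusted p = 4.6e-10, and 0.23 with an estimated correlation). S-Lap7 (3577 ± 289.7 against 0.697 ± 0.283, log2 fold 8.39 ± 0.07), ocn (8.35 ± 0.09) and the sperm protein Mst98Ca (8.17 ± 0.09) were higher and twe (-2.93 ± 0.10) and bam (-2.40 ± 0.10) lower. Of 33 oogenesis genes 28 fell and 1 rose (the same adjusted over the list alone, adjusted p = 3.8e-05, and 0.057 with an estimated correlation). The posterior determinant osk (2.33 ± 2.18 against 2035 ± 106, log2 fold -7.39 ± 0.12) and otu (-6.41 ± 0.07) fell, and exu (6.45 ± 0.11), by its brightest probe set, rose. All 23 cell cycle genes fell (23 adjusted over the list alone; adjusted p = 7.7e-06, and 0.099 with an estimated correlation). An example is Orc1 (log2 fold -5.50 ± 0.06). Eggshell genes Vm34Ca (log2 fold -8.10 ± 0.12) and Cp38 (-7.96 ± 0.10) fell most.

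Mated and virgin spermathecae, both amplified in 2 rounds, differed in 32 higher and 57 lower probe sets of 11496. Listericin (387 ± 167 against 28.8 ± 6.93, log2 fold 3.28 ± 0.27), an antimicrobial peptide gene, CG5246 (3.01 ± 0.35) and CG8112 (2.12 ± 0.21) rose. The storage protein Lsp2 (69.0 ± 47.5 against 993 ± 408, log2 fold -3.79 ± 0.45), the glucosidase tobi (-2.50 ± 0.21) and Cyp309a1 (-2.11 ± 0.23) fell. None of the 4 tested spermathecal secretion genes (adjusted p = 0.34), 6 seminal fluid genes (adjusted p = 0.9) or 10 antimicrobial peptide genes (adjusted p = 0.78) passed limma's test, nor adjusted over the list alone (2 of each at an unadjusted p under 0.05). Send1 stood at 6515 ± 462 against 6281 ± 503 (adjusted p = 0.82). Camera pointed down for the seminal fluid list, whose median log2 fold was 0.15 and mean 0.03, and for the antimicrobial list, with 0.07 and -0.05. With the redone arrays in place of the first, 558 probe sets were called and 13 of 25 named genes lost their call, the 6 just named among them (log2 folds 0.83, 1.47, 0.18, -0.81, -1.82 and -1.51) and Root (1.53 ± 0.13) turning to -0.37. With both sets and amplification as a covariate limma called 0 probe sets (501 at an unadjusted p under 0.05). Without redone replicate 2, an alternative added after seeing the data, the counts were 997 and 34. With the redone arrays 16 of the 25 then held, Listericin (1.62) and CG5246 (2.73) among them, and Lsp2 and CG3699 stood at 0.07 and 0.15.

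Of the redone mated arrays 3 of 4 had another amplification than the first set. Against that set 149 probe sets were higher and 232 lower, but the count hung on single arrays: 1006 in all without redone replicate 2, 72 and 66 without replicates 3 and 4, and 29, 43, 27 and 183 without replicates 1 to 4 of the first set. A replicate block gave 13 and 1 fit of all groups 1482. RpS29 (8927 ± 1833 against 626 ± 193, log2 fold 3.84 ± 0.27), a ribosomal protein, and scyl (3.18 ± 0.20) rose, and CG32212 (-3.32 ± 0.21) and rdgB (-2.60 ± 0.29) fell. None of the 4 tested spermathecal genes passed limma's test (1 at an unadjusted p under 0.05, 0 higher and 1 lower adjusted over the list alone; adjusted p = 0.5), with Send1 at 7710 ± 5215 against 6515 ± 462 (adjusted p = 0.6). Send2 turned from -0.44 (adjusted p = 0.91) to 1.92 (0.012) without redone replicate 2, and was then the 1 gene of the list that rose. Of 22 muscle genes 1 rose (1 adjusted over the list alone; adjusted p = 0.018, and 0.9 with an estimated correlation; 0.97 without replicate 2, 0.082 after quantile normalization and 0.062 with the mean of all probe sets of a gene). It was Msp300 (log2 fold 1.51 ± 0.24), which lost its call with a replicate block and without any 1 of 5 arrays. Of 37 tested ribosomal protein genes 3 rose with all arrays (5 adjusted over the list alone; adjusted p = 3.5e-10, and adjusted p = 0.64 with an estimated correlation; the direction turned after quantile normalization, 0.86), and 8 rose and 1 fell without redone replicate 2 (adjusted p = 3.6e-13, and adjusted p = 0.76 with an estimated correlation).

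Across the dissected adult tissues 3105 probe sets were restricted to 1 tissue, lying at least 4-fold above every other tissue. The testis held 1552, the ovary 359, the midgut 312, the central nervous system 287, the accessory gland 211 and the eye 105. Wing held 76, ejaculatory duct 58, hindgut 52, salivary gland 46, crop 20, trachea 18, carcass 7, fat body 1 and heart 1. Low counts need not mean few specific genes. The heart's 4 leading genes also led in trachea. Fat body genes rose in heart and carcass (17 and 13 of 19, 1 fell in each). Thoracic muscle and spermatheca held 0, and 221 and 19 without thoracic muscle replicate 4 and redone replicate 2, when the total was 3332; ratios of 2 and a minimum level 5 times higher gave 4691 and 1826. Among those with the highest ratios were Cpr72Ec in the eye (6412 ± 553), lectin-46Ca in the accessory gland (8093 ± 576), the protease Jon65Ai in the midgut (4676 ± 355) and bcd in ovary (1028 ± 43.4). Their next tissue stood at 16.97 or less, near the pseudocount, so no ratio is given. LysP stood at 78.5 times the next tissue in salivary gland, and FMRFa at 60 times in the nervous system (45.4 without the 2 arrays).

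**Figure D5:**
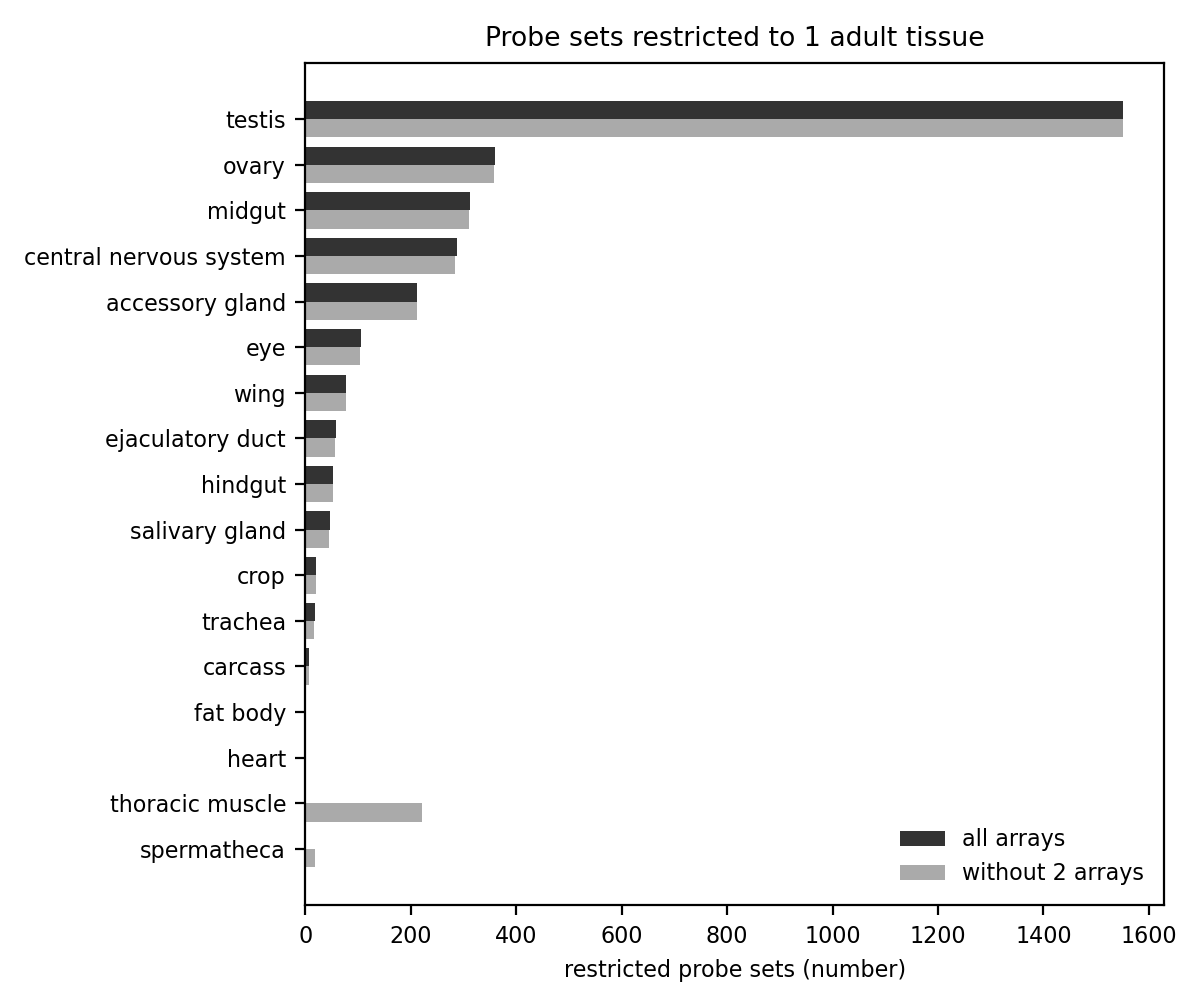
Number of probe sets restricted to each of 17 dissected adult tissues with all arrays (dark) and without thoracic muscle replicate 4 and redone spermatheca replicate 2 (light). The testis bar stands at 1552 and the muscle bar at 0 and, without the 2 arrays, 221.

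Of 46 measured fly homologs of 67 listed disease genes, 37 (80.4%) were called higher in their top tissue than in the whole fly. Picking the top tissue favours such a call: of 10664 other genes chosen alike, at levels within the range of the homologs, 83.1% were called (Fisher p = 0.56). Thoracic muscle was the top tissue of 12, the brain of 8 and the eye of 5. Large folds were those of hgo (alkaptonuria) in the wing, at 1551 ± 135 against 60.1 ± 19.1 and a log2 fold of 4.51 ± 0.17, Appl (Alzheimer disease) in the brain (4.02 ± 0.10) and Npc1a (Niemann-Pick disease type C) in the ejaculatory duct (3.26 ± 0.14). Of the 9 not called, 7 had thoracic muscle as top tissue, such as Pink1 (Parkinson disease), at 2597 ± 1619 against 346 ± 24.4. Without the 2 arrays in doubt 43 were called, Pink1 among them, and after quantile normalization 37, with 5 gained and 5 lost.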

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

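Except for the whole-array shift, the interactions and the regrouping of arrays other than that within tissues, the tests in this part were chosen only after the result was seen. Arrays were named here when 1 of 4 lay far from the other 3 by Dixon's ratio, which chance gives in about 1 in 20 groups: 16 of 102 groups of array measures, 6 of 65 of list means and 17 of 282 of named genes in the first group of their comparison.

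In the array labelled thoracic muscle replicate 4 the muscle list stood at 7.00 on the log2 scale and in the 3 others between 11.07 and 11.31, and its mean correlation with its group was 0.781. In the array labelled redone spermatheca replicate 2 the muscle list stood at 11.43, the spermathecal list at 4.31, Msp300 at 369.9 and the mean correlation at 0.769. A candidate explanation is an exchange of the labels of these 2 arrays: the first correlated at 0.975 with the 3 other redone arrays, and the second at 0.939 with the 3 other muscle arrays, where the lowest values among those arrays themselves are 0.972 and 0.932. A mixture of the 2 RNA samples is argued against: in the array labelled thoracic muscle replicate 4 the 15 abundant muscle genes reached 2.92% of their muscle level, against 1.67% in the 3 other redone arrays. No biological explanation was tested, and no array was moved to another group.

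In larval fat body, the mean correlation of feeding replicate 4 was 0.924, and in wandering replicate 2 the glue list stood at 4.28 and the 10 brightest probe sets held 2.32% of signal. A candidate explanation for the testis transcripts is RNA from larval testes, which lie in the fat body: 95.5% of the 200 most abundant testis-restricted probe sets stood at least 4-fold above the other feeding arrays in feeding replicate 4, while 0% of the ovary-restricted ones did, which argues against a shift of the whole array. A change with wandering is argued against in feeding replicate 4, an array of feeding larvae. For the wandering arrays it cannot be told apart: all 4 lay above the 3 other feeding arrays, and 2 above feeding replicate 4. Larval testis was not analysed here, so the adult testis stands in for it.

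The glue transcripts of wandering fat body replicates 1, 3 and 4 may come from salivary glands left on the tissue. Glands like those of feeding larvae are argued against: the glue genes ng1, ng2 and ng3 had a median of 0.146% of the level that the gland share given by Sgs3 would bring. Glands of wandering larvae cannot be told apart from other sources, as none were analysed here; of the 50 other most gland-enriched probe sets 8% stood at least 4-fold above the feeding fat body. Nor can a change of the fat body with wandering: Sgs3 stood above every feeding array in 3 of 4 wandering arrays, and replicate 2, a single array, excludes nothing.

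Other arrays lay apart as follows. The median signal was 20.4 in salivary gland replicate 1 and 8.97 in eye replicate 4. The share of the 10 brightest probe sets was 1.84% in head replicate 1, 1.87% in larval hindgut replicate 2, 2.12% in heart replicate 3 and 2.45% in ejaculatory duct replicate 2. The mean correlation with the own group was 0.989 in brain replicate 4, 0.987 in wandering tubule replicate 2, 0.958 in salivary gland replicate 1, 0.983 in larval salivary gland replicate 4, 0.976 in ejaculatory duct replicate 2 and 0.988 in whole larva replicate 2. The ejaculatory duct list stood at 12.73 in duct replicate 2, and the ribosomal list at 10.42 in S2 replicate 1.

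Among named genes single arrays stood apart for a10 (2992, head replicate 3), ACC (76.3, wandering fat body replicate 4), CG10553 (106, wandering tubule replicate 3), CG33109 (10.7, larval salivary gland replicate 3), Dscam2 (28.2, larval CNS replicate 1) and Ebp (7528, duct replicate 2). Others were Fad2 (8.26, larval carcass replicate 4), Gasp (1070, trachea replicate 2), inaD (4241, eye replicate 1), Jon66Cii (5871, larval midgut replicate 4), Obp56g (32.6, wing replicate 1) and onecut (312.7, larval CNS replicate 2). Pdf stood at 938 in brain replicate 4, Send1 at 5533 in virgin spermatheca replicate 4, Vha100-2 at 3320 in larval hindgut replicate 3, and Yp1 at 8.08 in testis replicate 3.

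By interaction tests, 1047 probe sets differed between fat body and tubule in their wandering effect. The largest differences were 7.67 ± 2.42 for Sgs7, 7.41 ± 2.33 for Sgs8, 7.17 ± 0.30 for CG9812 and 6.81 ± 2.11 for Sgs4 (log2 folds of the 3 Sgs genes in tubule -2.70, -2.69 and -1.99; Sgs7 at 46.5 in wandering fat body replicate 2, which lacked glue), and -3.89 for Ugt37A3, -3.98 for CG15890, -4.29 for GstT3 and -4.51 for Had2. Between midgut and hindgut 2025 differed in their stage effect, with 9.06 for CG5084, 9.04 for CG10154, 8.15 for CG33128 and 8.14 for CG34282, and -7.74 for CG34324, -7.78 for CG3906, -8.06 for CG5107 and -8.14 for CG17192. Of 100 splits of the arrays within each tissue, 4 and 1, the real one included, gave as many. The highest others gave 1619 and 1669. These splits mix stages, with a median residual SD of 0.338 and 0.302 against 0.265 and 0.197 in the real groups. So chance is not said to be excluded by them. For fat body against tubule the highest parts the fat body arrays as the other split given below does. Of 100 splits across the tissues 2 and 3 gave as many. These do not test the stage, since they mix tissues (median residual SD 0.456 and 0.389). Their highest, 5061 and 3088, set 7 of the 8 arrays of 1 tissue against 7 of the other, which points to a structure of the samples.

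In 43 of the 44 comparisons only the real split, 1 of 35, gave as many called probe sets. Any other split gave at most 5 calls (larval against adult trachea, 3726 real), and 1 against 89 for mated against virgin. Where the groups differ, every other split mixes them, which widens the spread within its groups and leaves few calls. A share of 2.86% is also the lowest that 1 comparison can give, and it was not adjusted over the 44. The arrays thus part by their labels, and chance is not said to be excluded. For wandering against feeding fat body 2 of 35 splits gave as many, so this count does not exclude chance: the real split gave 1067 and the other 1549. That split parts the arrays by their testis transcripts, and 1319 of its called probe sets are testis-restricted against 21 in the real split, which points to a structure of the samples.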

How the results depend on the processing

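In this part the tests without 2 arrays in doubt, gene lists and homologs with arrays left out, and mated sets with 1 array left out were chosen only after seeing the result. A count, higher and lower together, holds within 1.5 times its value in the report. A gene or list holds when it keeps its direction and side of the threshold. All 48 counts held with values as deposited and after quantile normalization. After the latter the share higher in adult tissues moved from at most 38.7% to at least 45.8%. All 46 held without a filter and with the 60th percentile one. So did 46 of 47 with a pseudocount of 2%, 45 of 46 with a replicate block and 43 of 46 in 1 fit. Signal over background limits the rest: with a pseudocount of 40%, which pulls low signals together, 7 of 47 held.

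With that pseudocount the probe sets called against the whole fly were 3152 in hindgut, 3458 in midgut, 3425 in crop, 3759 in salivary gland, 4484 in brain, 4251 in ganglion, 3241 in head, 3690 in eye, 3241 in ovary, 3697 in accessory gland, 3271 in ejaculatory duct, 3674 in virgin, 3487 in first mated and 2794 in redone spermatheca, 3503 in fat body, 3504 in heart, 3115 in carcass, 3067 in trachea, 3156 in thoracic muscle, 3405 in wing and 3815 in S2 cells. Against the whole larva they were 1658 in hindgut, 1865 in midgut, 2992 in salivary gland, 2569 in tubule, 1750 in carcass, 4294 in CNS and 2422 in trachea. Between larva and adult they were 750 in midgut, 1188 in hindgut, 1672 in salivary gland, 1326 in fat body, 2422 in trachea, 2251 for CNS against brain and 2411 for whole animals. For wandering larvae they were 689 in fat body and 533 in tubule, for the redone set 214, and for the wandering and stage interactions 677 and 1298. A pseudocount of 2% gave 1890 for the midgut stages.

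In 1 fit of all groups the wandering fat body gave 2444, its interaction 2283 and the redone set 1482. With a replicate block the redone set gave 13; the cause of these was not tested. Without the 2 arrays highest in testis transcripts the wandering fat body gave 2224 and the interaction 2184. Mated against virgin spermatheca gave 558 with the redone arrays in place of the first, 997 with 1 of them left out, 0 with both sets and amplification as a covariate (501 of 11559 at an unadjusted p under 0.05 in limma) and 34 with that and 1 array left out; the cause was not tested. Restricted probe sets numbered 4691 at a ratio of 2 and 1826 at 5 times the minimum level.

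With each array left out in turn 382 of 392 counts held. The others were those of the wandering fat body (909 to 2170, the highest without feeding replicate 4), the redone set (27 to 1006, the highest without redone replicate 2) and the wandering interaction (948 to 2183, the highest without feeding fat body replicate 4, and 1743 without wandering replicate 1). Homologs called ranged from 34 to 43.

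Of 92 list results 81 held after quantile normalization, 85 with the mean of all probe sets of a gene and 26 with an estimated correlation between genes; 726 of 736 held with an array left out. The muscle list turned direction after quantile normalization in heart (adjusted p = 0.81) and thoracic muscle (0.88), and the ribosomal list in the redone set (0.86). For the muscle list, over its alternatives the adjusted p ran from 0.0024 to 0.81 in heart and from 1.4e-05 to 0.88 in thoracic muscle; the cause was not tested.

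Of 804 named gene results all held with values as deposited, 761 of 803 after quantile normalization, 780 of 800 and 772 of 804 with pseudocounts of 2% and 40%, 792 without a filter, 788 in 1 fit, 783 with a replicate block and 6349 of 6552 with an array left out. Turned in direction were Eglp2 in virgin spermatheca (0.08 after quantile normalization), Root (-0.37) with redone arrays in place, Lsp2 (0.07) and CG3699 (0.15) with 1 of those left out, and Send2 in the redone set (1.92 without replicate 2, which lacks its transcript, and -1.28 at the least with another array left out); for the first 4 the cause was not tested. The planned counts per chromosome were not run.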

Other observations

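The list tests and the genes named in this part were chosen only after the result was seen, and no explanation was tested. Cytochrome P450 genes were counted in 3 tissues, with no test between them. In the head 20 of 38 tested rose and 2 fell (adjusted p = 9.7e-06, and 0.12 with an estimated correlation), with Cyp4g15 (log2 fold 3.34 ± 0.11) higher and the hydrocarbon-making Cyp4g1 (log2 fold -7.04 ± 0.30) lower. In the ovary 2 of 38 rose and 24 fell (adjusted p = 9e-05, and 0.15 with an estimated correlation), and in the larval salivary gland, against the whole larva, 1 of 34 rose and 30 fell (adjusted p = 1.1e-07, and 0.037 with an estimated correlation).

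Of 9 genes of sex determination and dosage compensation 6 rose and 1 fell in the brain (adjusted p = 0.021, and 0.14 with an estimated correlation), among them fru (log2 fold 2.99 ± 0.10) and mle (log2 fold 2.48 ± 0.14). In testis 5 fell and 0 rose (adjusted p = 0.2), an example being msl-3 (log2 fold -2.31 ± 0.18). Of 14 immune recognition genes 7 rose and 1 fell in the wing (adjusted p = 0.0019, and 0.39 with an estimated correlation), with GNBP2 (log2 fold 3.66 ± 0.10) higher and PGRP-SC2 (log2 fold -5.07 ± 0.21) lower. Hemocyte genes (9 of 18 rose and 1 fell, adjusted p = 0.00018) and tracheal genes (7 of 15 rose and 1 fell, adjusted p = 0.0044) moved with them there, each at 0.39 with an estimated correlation.

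Yolk protein transcripts differed between dissected tissues of mixed sex: Yp1 stood at 15890 ± 3709 in thoracic muscle (with replicate 4, in doubt), 8882 ± 804 in the eye and 2788 ± 377 in the brain, against 4739 ± 808 in the whole fly and 4.60 ± 2.34 in the testis. Against the whole fly 2 of 3 yolk genes rose in muscle and trachea, 0 were called in eye, head, heart and wing, and 2 fell in brain and crop. In larval fat body all 3 genes of larval serum and metamorphic fat body rose (adjusted p = 0.032, and 0.4 with an estimated correlation; 0.56 after quantile normalization and 0.051 with the mean of all probe sets of a gene), with Lsp2 at 9096 ± 1180.

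Ribosomal protein genes split between the gonads: 31 of 40 were lower in testis and 7 higher (adjusted p = 0.011, and 0.46 with an estimated correlation), with the duplicate RpL10Aa (log2 fold 6.79 ± 0.07) higher and RpL27 (log2 fold -3.05 ± 0.07) lower.

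Replicate 1 of the whole fly held the eggshell list at 8.71 on the log2 scale and the 3 others between 9.91 and 10.28.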
